A study of Homo sapiens with 1188 samples.

How the data were processed

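RNA was measured in 1188 single HUES64 cells by Smart-seq 2 with Illumina Nextera XT libraries, per the labels' protocols. The deposited values were TPM per cell, normalised by transcript length and total, and the submitters' processing notes name bcl2fastq, TopHat and RSEM without versions and the hg38 genome build. The annotation release, the use of strand and the treatment of reads shared between genes are not given in the sources used here. The table held 30311 genes, of which 398 shared a symbol with another and were kept apart by identifier, and column totals ran from 963273 to 1000000. Of the gene identifiers, 29317 (96.7%) matched GENCODE 29 on GRCh38 without the version number, which supplied the coordinates printed, and 96.0% matched the supplied table of gene names. Deposited cells had 1017 to 15508 genes at 1 TPM or more, and read counts and depths were not analysed here, so no counting interval on expression can be given.

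Each cell belongs to a culture named by genotype, cell state and replicate number, and the culture, not the cell, was the replicate. Of the 13 cultures 2 were WT ES, and every other group had 1. A culture here means all cells of 1 group and replicate number. Whether the 2 WT ES sets were grown apart is not established here, so their spread may understate that between separate cultures. The 3AKO cells were labelled clone #139 and the DKO cells clone #21, and no batch or date label was given. The culture described as DKO ES cells carried a day 5 tag and was kept with the ES cells. Cells with fewer than 2000 detected genes, 32 in all and 0 to 5 per culture, were left out, no doublet caller was run, and no identical cells were found. Choices of grouping, comparisons, gene lists, naming rule and alternatives were fixed before the data were examined, apart from the cells matched between compared cultures and the tests of explanations that the closing section names as chosen later. The limma counts of list members were not among those fixed choices.

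Mean TPM over cells was computed per culture, and differences were taken on log2(mean TPM + 1), with WT ES as the mean of both cultures at equal weight. A gene was counted as higher or lower when its difference reached 1 (2-fold) and the higher group mean was 5 TPM or more, and the same count was made between the WT ES cultures. For 3AKO ES, DKO ES and DNMT1 KO day 0 against WT ES, limma 3.58.1 (R 4.3.3) fitted log2(mean TPM + 1) per culture. It used a two-sided moderated test, an intensity trend and Benjamini-Hochberg adjustment at 0.05. The 14059 genes tested had 5 TPM or more in at least 1 culture of WT ES, 3AKO ES, DKO ES or DNMT1 KO day 0. Some were therefore below 5 TPM in both groups of a comparison. The spread came from 1 residual degree of freedom, so lone cultures were assumed to vary like the WT ES cultures. The other 12 comparisons were planned by size only, without a test. For each of 15 comparisons, the median of each of 39 gene lists was set against 10000 random lists matched on mean expression in 20 bins. Of these medians only 2 are printed, each above all random lists, and how many others lay outside the random range is not reported. Counts of list members called by limma were not tested against the share of all genes called. These counts, and those adjusted over a list alone, were not corrected for the number of lists and comparisons. In the housekeeping list 4, 2 and 3 of 25 genes rose and 6, 4 and 6 fell in 3AKO ES, DKO ES and DNMT1 KO day 0.

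Genes were named by rule: per comparison, the 10 with the largest positive and the 10 with the largest negative difference, among genes with 10 TPM or more in the higher group and detected in 10% or more of its cells, and against WT ES also outside the range of both WT ES cultures. Genes with a clone, LOC, LINC, small RNA, ribosomal protein pseudogene or mitochondrially encoded gene name were left out, by name and not by gene type, so long intergenic RNAs with other names stayed. Members of the fixed lists and the DNA methylation genes were named besides, list members by the size of their difference. Values of some genes that the rule or the lists would name are not reported. A gene at 0 in every cell of a group is called listed at 0, with no difference given.

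Distance between cells was the median over cell pairs of 1 minus Spearman's correlation, over 8927 genes with a mean of 10 TPM or more. Its SE among matched cells was the SD over random draws of 50% of the cells, which covers counting error only. Squared coefficients of variation were compared over genes of 10 TPM or more whose means lay within 2-fold. Shares of cells at 10 TPM carry exact Clopper-Pearson 95% intervals, and a share of 0 the limit that 3 counts allow. Overlaps were set beside independent lists and 100 simulated unchanged cultures sharing the WT cultures. The simulated spread came from the WT ES pair at every stage. Alternatives covered the pseudocount, the filter, the scaling, the cells used, the averaging, the limma options and leaving out each WT ES culture.

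The limma test, the size rule, the list percentiles and the distance between cells were tried on simulated data, and other steps were not. Apart from the distance trial, every simulated culture had the spread of the WT ES pair, set by expression level alone. Genes of low expression were left out of those changed. The trial therefore could not test the intensity trend, or whether lone cultures vary like WT ES. In a simulated 3AKO ES comparison of 12709 genes, limma recovered 79% of 100 genes changed by 1 and 100% of 100 changed by 2, with 12 calls among unchanged genes. The size rule passed 54% and 100% of them, and passed 169 of 11825 unchanged genes in a simulated DKO ES comparison. In that comparison 4.5% of unchanged lists lay outside the middle 95% of random lists. Genes varied independently there and the lists were drawn at random. The trial therefore could not show how often lists of genes that vary together lie outside. A simulated culture with 20% of values set to 0 had a distance of 0.727, against 0.344 without, so missed detection raises this measure. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.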

Results

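Single cells of HUES64, an established human embryonic stem (ES) cell line, were profiled with Smart-seq 2, a full-length RNA-seq method that makes 1 library per cell. The 1188 cells came from 13 cultures in 12 groups. Wild-type (WT) ES cells had 2 cultures, with 88 and 92 cells. A culture here is all cells of 1 group and replicate number, and the 2 WT ES sets may not have been grown apart. Every other group had 1 culture: WT, 3AKO and DKO clones as ES cells and after 5 days of differentiation to dEC or dME, and cells labelled DNMT1 KO with doxycycline at days 0, 2 and 8. The labels do not spell out 3AKO, DKO, dEC or dME, and the series title names DNMT3A/B, the de novo DNA methyltransferases. The DKO ES culture was described as ES cells but tagged as day 5, and was grouped by its description. Cultures held 86 to 95 cells, of which 1156 in all had 2000 or more genes at 1 TPM and were used. TPM keeps no sequencing depth, so precision is described by the number of detected genes, whose culture medians ran from 7547 at DNMT1 KO day 8 to 12310 in WT ES replicate 1. Levels are culture means of TPM, and differences are those of log2(mean TPM + 1), which understate the change of low genes. Only WT ES had replicates, and differences outside the ES comparisons were planned by size alone, without a test. Genotype, clone and culture cannot be separated in this design, and every p value measures spread only between these samples.

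The targeted genes were examined first. DNMT3A (chromosome 2, 25227855 to 25342590, minus strand) had a mean of 65.0 ± 2.56 TPM in WT ES (SD, n = 2 cultures), against 8.06 in 3AKO ES and 5.43 in DKO ES. It fell by 2.86 in 3AKO ES (SE 0.20, adjusted p = 0.00533 by limma) and by 3.36 in DKO ES (SE 0.20, adjusted p = 0.00571 by limma). It was 52.5 in WT dEC, 10.01 in 3AKO dEC and 9.46 in DKO dEC, and 36.4, 11.6 and 4.73 in the WT, 3AKO and DKO dME cultures. DNMT3B (chromosome 20, 32762385 to 32809356, plus strand), highly expressed in pluripotent cells, had 189 ± 7.74 TPM in WT ES (n = 2), 106 in 3AKO ES and 78.2 in DKO ES. Its transcript was detected at 1 TPM in 95.6% of DKO ES cells (exact Clopper-Pearson 95% interval 89.0 to 98.8, counting error only), so mRNA level did not check the DKO label for this gene. DNMT1 (chromosome 19, 10133345 to 10231286, minus strand), the maintenance methyltransferase, had 141 TPM at DNMT1 KO day 0, near the WT ES mean of 132 ± 11.02 (n = 2). It was lower at day 2, with 41.4 TPM, and at day 8, with 50.1 TPM, so the day 0 culture carried WT-like DNMT1 mRNA.

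**Figure D1:**
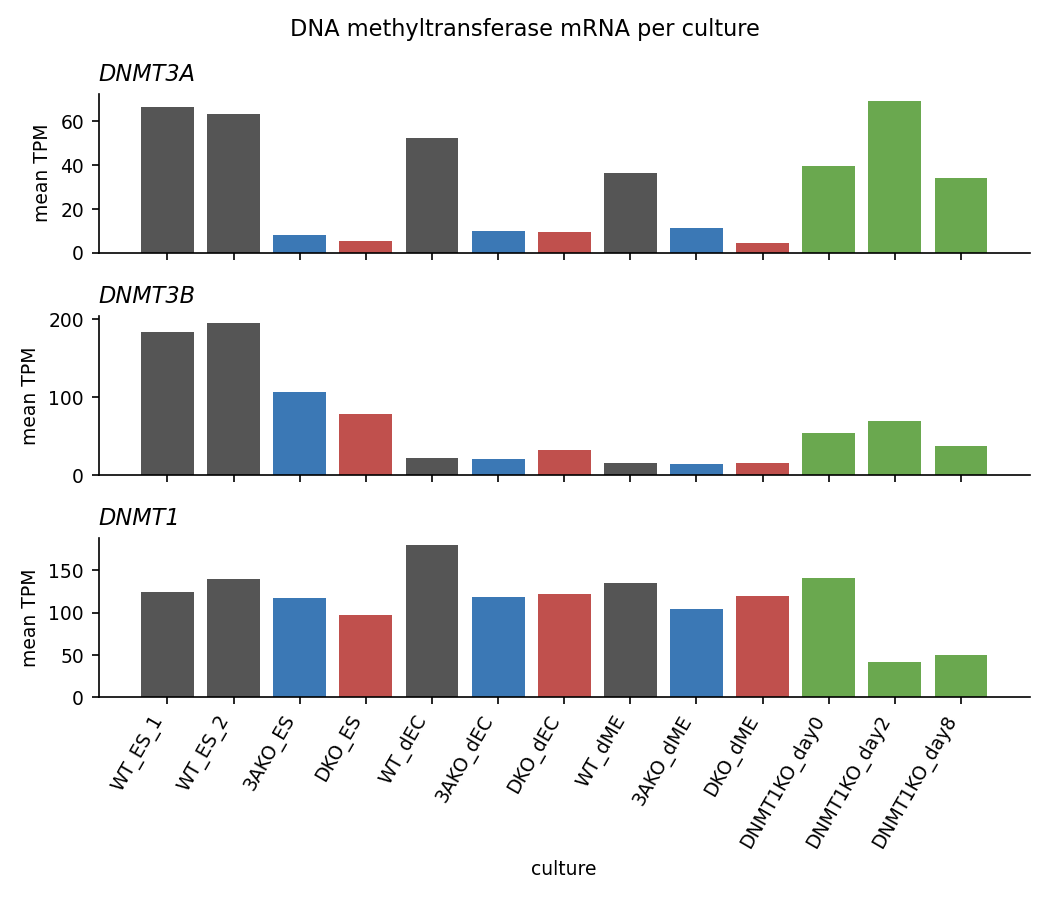
Mean TPM of DNMT3A, DNMT3B and DNMT1 (vertical axis, linear from 0) in each of the 13 cultures, 1 bar per culture. DNMT3A is at or below 11.6 in every 3AKO and DKO culture, and DNMT1 drops from 141 to 41.4 between DNMT1 KO days 0 and 2.

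In 3AKO ES cells, genes of the NODAL pathway fell, and so did markers of other cell states. NODAL itself, the TGF-beta family ligand that maintains primed human pluripotent cells (ENSG00000156574.7, chromosome 10, 70432315 to 70447951), fell from 75.8 to 0.0275 TPM, a difference of -6.21 with SE 0.26 (limma adjusted p = 0.00292). Its feedback inhibitors LEFTY1 (-5.98, adjusted p = 0.00292 by limma) and CER1 (-5.86, adjusted p = 0.0183 by limma) fell as well, as did GDF3 and SKIL. Of 14 tested NODAL and TGF-beta genes, 10 fell and 0 rose at an adjusted p under 0.05 in limma, and 11 fell when adjusted over the list alone. Primitive streak genes fell at 3 of 5 tested, mesoderm at 3 of 6, endoderm, whose list includes CER1, at 2 of 5, and amnion or trophoblast genes at 3 of 7, with 0 rising (5, 3, 2 and 3 fell adjusted over the list alone). The lists share genes, so their counts are not independent. NODAL is also in the primitive streak list, HAND1 in the mesoderm and amnion lists, and TDGF1 and GDF3 in the NODAL and pluripotency core lists. TBXT, of the primitive streak, was at 10 TPM or more in 5 of 88 and 8 of 90 WT ES cells and in 0 of 92 3AKO ES cells, so loss of a differentiating subset present in WT ES stays open for these genes. ZFP42, the pluripotency-associated zinc finger REX1 (ENSG00000179059.7, chromosome 4, 187995771 to 188005050), fell by 5.74, from 137 to 1.58 TPM. In the pluripotency core list 11 of 18 fell and 0 rose (13 adjusted over the list alone), among them NANOG (-1.69), PRDM14 (-1.79) and TDGF1 (-1.33), while SOX2 (0.22, adjusted p = 0.707 by limma) passed no test.

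Targets of FGF and ERK signalling were lower in 3AKO ES: 9 of 15 fell and 1 rose (10 and 1 adjusted over the list alone), including MYC (-2.93), DUSP6 (-1.86) and ETV4 (-1.75). In the unfolded protein response list 9 of 16 fell and 0 rose (11 and 1 adjusted over the list alone), with the chaperone HSPA5 at -1.58 and the glucose-and-amino-acid stress gene TRIB3 at -1.71. In the mesenchymal list 7 of 16 fell and 1 rose (11 and 1 adjusted over the list alone): CALD1 (-2.04) and VIM (-1.49) fell and LGALS1, galectin-1, rose (2.40). Ribosomal protein genes went the other way, with 56 of 82 rising and 1 falling (75 and 1 adjusted over the list alone), a list median of 0.54, above all 10000 random lists matched on expression. The sign of this median was the same after median-ratio rescaling, and the list's share of TPM was 23.8% in 3AKO ES against 16.6% and 15.3% in the WT ES cultures.

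Other genes with large falls in 3AKO ES were the paternally expressed imprinted gene NNAT (-6.00), the secreted phosphoprotein SPP1 (-5.38), cardiac actin ACTC1 (-5.31), the hyaluronan synthase HAS2 (-4.68) and the phosphatase DUSP23 (-4.59). ANXA1, annexin A1, was listed at 0 against 61.9 TPM in WT ES, and the cystatin CST1 was listed at 0 against 7.59 and 343 TPM in the WT ES cultures, a spread too wide for a call (adjusted p = 0.107 by limma). Large rises included LHX5-AS1 (4.59), RNF212 (3.68), a meiotic crossover factor, SMIM24 (3.24), the imprinted DLK1 (2.95), the forebrain factor FEZF1 (2.89), BST2 (2.86, 206 against 27.6 TPM, adjusted p = 0.00363 by limma), an interferon-induced antiviral protein, SPINK2 (2.83), the chemokine CXCL5 (2.62) and ZP3 (14.7 against 1.79 TPM), a zona pellucida glycoprotein. HORMAD2-AS1 (2.51) also rose, and LHX5-AS1 and HORMAD2-AS1, as antisense genes, could not be told from overlapping transcripts because strand use is not given in the sources used here. Over 14059 genes limma called 501 higher and 1207 lower (70.7% lower). The test rests on 1 residual degree of freedom from the WT ES pair and assumes that the lone cultures vary like that pair. Without the intensity trend it called 4 genes (3799 at an unadjusted p under 0.05), and without the filter on low genes 0 (6239 unadjusted).

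By size, 554 genes were higher and 1025 lower by 1 or more in 3AKO ES among 11945 compared, 64.9% lower. The WT ES replicates differed from each other at 260 and 116 of 11723 genes, or 3.21%. Rescaling each cell without mitochondrially encoded and ribosomal protein genes moved the median of all genes by 0.14. The share lower was then 43.5% with the filter applied after rescaling. Over genes passing it as deposited, without those classes, it was 49.3%, against 65.0% before rescaling. Median-ratio rescaling gave 61.2%. The size of the split therefore depended on the scaling, and its direction also on the genes compared.

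Among genes that rose in DKO ES were several expressed in the germline. DPEP3, a testis-expressed dipeptidase (ENSG00000141096.4, chromosome 16, 67975663 to 67980829), rose from 1.46 to 96.2 TPM (5.32, SE 0.34, adjusted p = 0.00571 by limma). CTCFL (3.98), the testis paralogue of CTCF, AURKC (3.35), a kinase of meiosis, and ZP3 (3.42) rose too. Of 9 tested germline genes 3 rose and 0 fell (4 and 0 adjusted over the list alone). In the unfolded protein response list 11 of 16 fell and 0 rose (13 and 0 adjusted over the list alone), led by CHAC1 (-3.89), a target of the transcription factor ATF4; ASNS (-1.73), PSAT1 (-1.68) and ATF4 itself (-1.25) also fell. SLC7A5, the large neutral amino acid transporter, fell by 3.95.

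NODAL in DKO ES was at 14.5 TPM (-2.30, adjusted p = 0.016 by limma) and LEFTY1 at 7.65 TPM (-2.92), while CER1, at 79.4 TPM, lay within the range of the WT ES cultures. In this list 5 of 14 fell and 0 rose (9 and 0 adjusted over the list alone), and in the pluripotency core list 6 of 18 fell and 0 rose (9 and 0 adjusted over the list alone), with ZFP42 at -5.53 and NANOG at 64.6 TPM, near its level in WT ES. Among markers of other cell states, primitive streak and endoderm genes each fell at 1 of 5, amnion or trophoblast genes at 1 of 7 and mesoderm genes at 0 of 6. With 0 rising, 1, 1, 2 and 3 fell adjusted over the list alone. TBXT was at 10 TPM or more in 1 of 90 DKO ES cells, against 5 of 88 and 8 of 90 in WT ES. Whether 3AKO and DKO differ in any of these lists was not tested. NNAT (-6.05), DUSP23 (-4.50), the acyltransferase AGPAT2 (-4.06), ANXA1 (-3.96), FAM71F1 (-3.86) and ACTC1 (-3.72) fell, and the transporter SLCO4A1 was listed at 0 against 12.4 TPM. TFF3 (4.96), the zinc importer SLC39A4 (3.82), the endogenous retroviral gene ERVH48-1 (3.72) and LGALS1 (3.34) rose, and TCL1A, at 10.9 TPM, was listed at 0 in WT ES. CST1, at 922 TPM, was not called (adjusted p = 0.217 by limma). In the glycolysis and hypoxia list 6 of 22 rose and 2 fell (6 and 3 adjusted over the list alone), with PDK1 (2.43) and BNIP3 (1.94) among them.

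For DKO ES limma called 536 genes higher and 844 lower, and without the intensity trend 0 (3698 at an unadjusted p under 0.05). By size 731 were higher and 787 lower of 12178 (51.8% lower), and 37.1% were lower when each cell was rescaled without mitochondrially encoded and ribosomal protein genes, a shift of 0.10 in the median of all genes. Without the filter limma called 0 (6091 unadjusted). Ribosomal proteins held 19.9% of TPM in DKO ES.

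The DNMT1 KO culture at day 0 was compared with WT ES as planned, and its DNMT1 mRNA was near the WT level. C7orf72, an uncharacterised gene (ENSG00000164500.6, chromosome 7, 50096036 to 50159830), was at 557 TPM and listed at 0 in WT ES. Testis-expressed X-linked genes RHOXF2B (7.26), MAGEA2 (4.25) and MAGEA2B (3.75) rose, and RHOXF2 was at 17.8 TPM against a listed 0; each of these has a near-identical copy with which reads could be split, so the single values are uncertain. The chemokines CCL5 (2.84) and CXCL11 (3.44), lysozyme LYZ (2.83) and the thiamine transporter SLC19A3 (2.95) rose, as did IQCH-AS1 (2.97), with the same doubt about strand. CBR1, carbonyl reductase 1 (chromosome 21, 36069941 to 36073166), fell by 5.54, from 121 to 1.61 TPM (SE 0.17, adjusted p = 0.00131 by limma). LEFTY1 (-4.96), ANXA1 (-5.00), NNAT (-4.89), DUSP23 (-4.85), NODAL (-4.39) and ZFP42 (-4.17) also fell, and CER1 was listed at 0. BNIP3P17, listed at 0 against 30.2 TPM, has a pseudogene name and is uncertain, and CST1 was not called (adjusted p = 0.0931 by limma).

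In the NODAL and TGF-beta list 11 of 14 fell and 0 rose in DNMT1 KO day 0 (11 and 1 adjusted over the list alone), in the pluripotency core 13 of 18 fell and 1 rose, ESRG at 1.31 (the same counts adjusted over the list alone), and in the BMP list 7 of 9 fell and 1 rose (7 and 1 adjusted over the list alone), with ID1 at -1.77. Of 7 neuroectoderm genes 6 fell (6 adjusted over the list alone), among them MEIS1 (-3.29) and HESX1 (-2.96). Markers of other cell states fell as well, primitive streak genes at 3 of 5, mesoderm at 3 of 6 and endoderm at 2 of 5, with 0 rising (4, 3 and 3 fell adjusted over the list alone), and TBXT was at 10 TPM or more in 0 of 89 cells. These lists share genes such as NODAL, CER1 and HAND1 with the others, so the counts are not independent. In the p53 list 5 of 26 rose and 2 fell (5 and 2 adjusted over the list alone), CDKN1A at 28.0 against 9.39 TPM and GDF15 at 1.79 being higher. The rising share of this list was near that over all genes tested. DNMT3B fell by 1.77. Over all 14059 genes limma called 2359 higher and 2191 lower, against 3506 in all without the intensity trend and 0 without the filter (8930 unadjusted). By size 2210 were higher and 1281 lower of 12901, 36.7% lower, but 56.2% were lower when log values were averaged over cells.

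**Figure D2:**
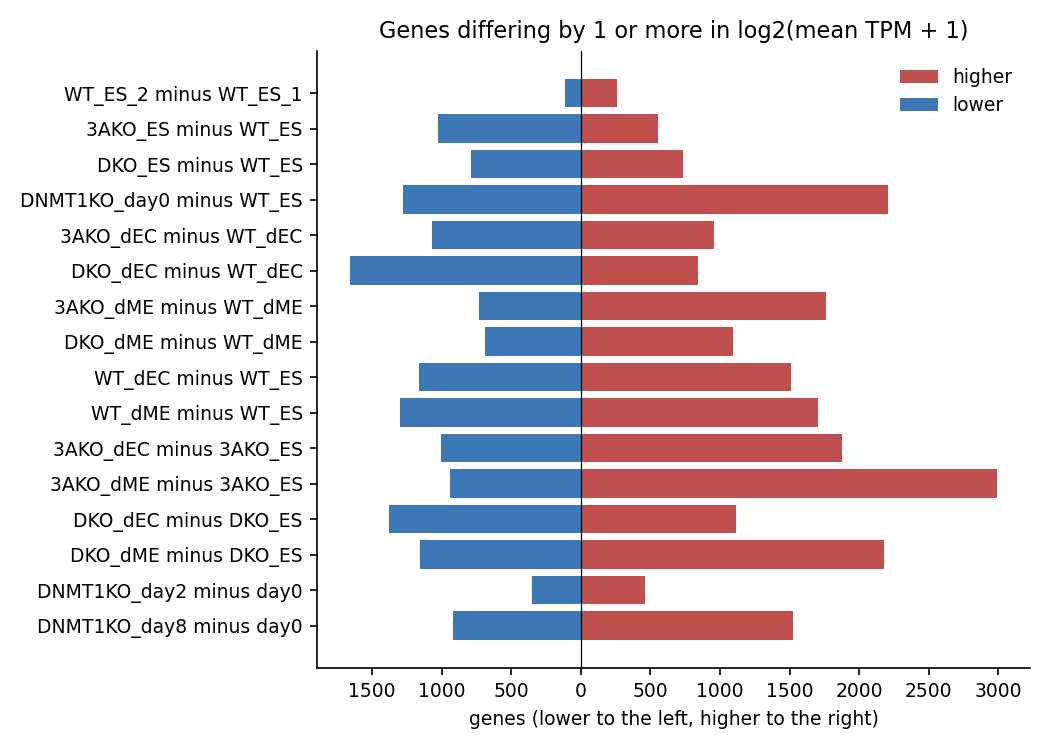
Number of genes higher or lower by 1 or more on the log2(mean TPM + 1) scale (horizontal axis) for the WT ES pair and each comparison (vertical axis), 1 pair of bars each. The WT ES replicates differ at 260 and 116 genes, and 3AKO dME minus 3AKO ES has the most, with 2993 higher and 937 lower.

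The genotype differences of 3AKO and DKO overlapped at each stage. In ES cells 367 genes were lower in both and 181 higher in both; independent lists would share 70.1 and 14.0, and simulated unchanged cultures that share the WT ES cultures gave means of 4.02 and 4.05. When 3AKO was set against WT ES replicate 1 and DKO against replicate 2, 320 genes were lower in both and 165 higher, and with the replicates exchanged 318 and 169. In dEC the numbers were 598 lower and 251 higher, against 147 and 27.2 for independent lists and 12.8 and 12.4 in the simulation. In dME 334 were lower and 509 higher, against 41.7 and 77.4 for independent lists and 15.8 and 15.8 in the simulation. Part of the excess in dEC and dME may come from the shared single WT culture, which cannot be split. The simulation used the spread of the WT ES pair, so it may understate chance overlap in dEC and dME. NNAT and DUSP23 were among the genes lower in every 3AKO and DKO culture: NNAT was at or below 0.31 TPM in each, against 251 in WT dEC and 99.6 in WT dME, and DUSP23 at or below 0.49 TPM, against 22.8 and 31.6.

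The series title asks about variability between cells, measured here as the median over cell pairs of 1 minus the Spearman correlation across 8927 genes. The distance was 0.380 and 0.423 in the WT ES cultures, 0.510 in 3AKO ES and 0.529 in DKO ES, differences of 0.108 and 0.128 from the WT ES mean beside an SD of 0.0309 between the WT ES cultures (n = 2). It was 0.543, 0.612 and 0.615 in the WT, 3AKO and DKO dEC cultures, 0.514, 0.604 and 0.570 in dME, and 0.445, 0.482 and 0.624 at DNMT1 KO days 0, 2 and 8. The knockout cultures also had fewer detected genes per cell: medians were 10765 in 3AKO ES and 10413 in DKO ES against a WT ES mean of 12048 ± 370 (SD, n = 2), 9033 and 8162 in 3AKO and DKO dEC against 10588, and 9498 and 9480 in dME against 10277. Among cells matched on detected genes the excess was 0.0506 in 3AKO ES and 0.0703 in DKO ES, 0.0198 and -0.0046 in dEC, and 0.0809 and 0.0157 in dME. DNMT1 KO day 0 itself lay above WT ES by 0.0465 (SE 0.0133) among matched cells, against 0.0434 unmatched. Against DNMT1 KO day 0 the matched difference was -0.0107 (SE 0.0209) at day 2 and 0.0494 (SE 0.0437) at day 8, against 0.0371 and 0.1791 unmatched. When cells were matched over all 13 cultures, at 14 cells per culture, the 3AKO ES difference turned to -0.0114, that of DKO ES was 0.0310, and that of DNMT1 KO day 0 turned to -0.0332. Among genes of like mean the squared coefficient of variation was higher than in WT ES replicate 2. The median log2 ratio was 0.42 in 3AKO ES, 0.69 in DKO ES and 0.49 in DNMT1 KO day 0. Against WT ES replicate 1 the ratios were 0.78, 1.04 and 0.87, and the WT ES replicates themselves differed by 0.34. The higher variation was therefore not particular to the 3AKO and DKO clones.

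**Figure D3:**
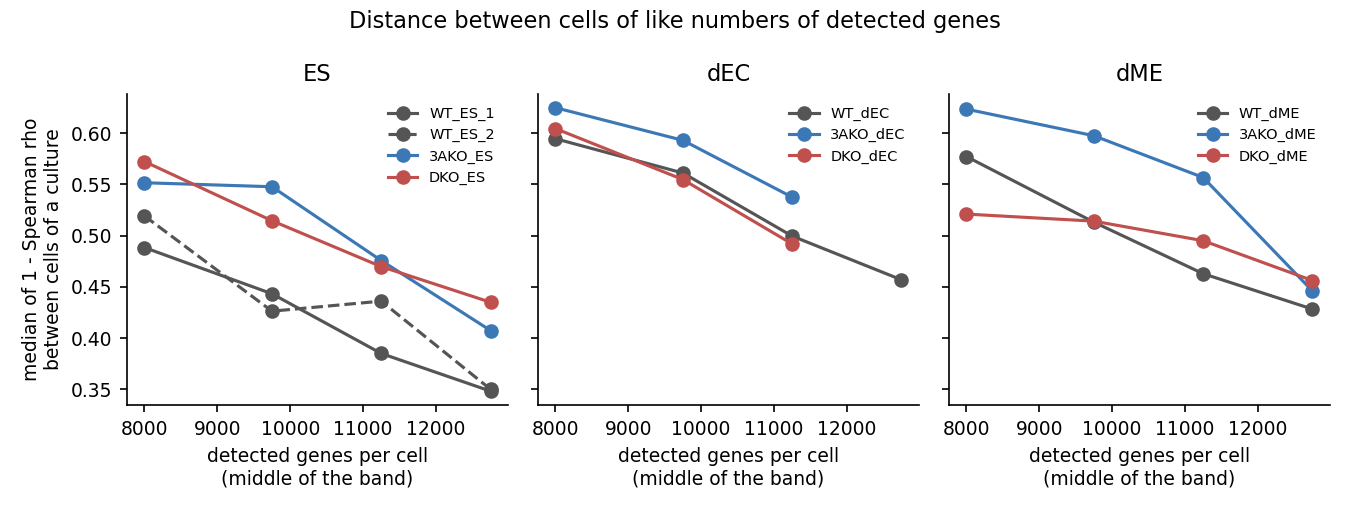
Median distance between cell pairs (1 minus Spearman correlation, vertical axis) within bands of detected genes per cell (horizontal axis), 1 line per culture, for ES, dEC and dME cells. In all 4 bands 3AKO ES and DKO ES lie above both WT ES cultures, by 0.0324 to 0.1045 and 0.0337 to 0.0850, while DKO dEC lies above WT dEC in 1 of 3.

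In dEC, 3AKO cells carried more neural crest and BMP transcripts and fewer epithelial ones than WT cells. All 6 neural crest genes that differed, of 9 compared, were higher, among them SOX9 (2.30), MSX1 (1.95) and TFAP2B (1.46), and 5 of 10 BMP genes were higher and 0 lower, including the antagonist NOG (3.43). FOXD3-AS1, beside the crest factor FOXD3, was at 52.5 TPM and listed at 0 in WT dEC, with strand again open. The protease KLK8 (4.06), BMPER (3.61), a secreted BMP regulator, the sensory neuron factor POU4F1 (3.43), RNF212 (3.27), TFAP2C (3.20), BST2 (2.95), the fructose transporter SLC2A5 (2.72) and SLCO1A2 (2.71) were also higher. NNAT and DUSP23 were listed at 0, and SPP1 (-6.10), ANXA1 (-4.90), the peptide adrenomedullin ADM (-4.64), the caveolae protein CAV1 (-4.34) and ANXA3 (-3.87) were lower. Epithelial genes were lower at 7 of 16 and higher at 1, with the tight junction gene CLDN7 at -4.04 and EPCAM at -3.83. The S phase list had 8 of 26 lower and 0 higher, such as MCM5 (-1.33) and PCNA (-1.04), and the FGF and ERK list 5 of 10 lower and 1 higher, DUSP6 at -3.04 and EGR1 at 1.41. In all 960 genes were higher and 1066 lower of 12726 (52.6% lower). The share lower was 40.0% when each cell was rescaled without mitochondrially encoded and ribosomal protein genes and 41.8% after median-ratio rescaling; the former moved the median of all genes by 0.14.

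In DKO dEC, epithelial genes were higher and stromal genes lower than in WT dEC, and neuroectoderm genes went both ways. HESX1 (193 against 8.38 TPM, 4.37), SIX3 (33.3 against 0.724 TPM, 4.31), FEZF1 (2.98) and LHX2 (2.67), transcription factors of the anterior neural plate, were higher, and POU3F2 (-2.44), NR2F1 (-1.88) and MEIS1 (-1.54) were lower, so 5 of 14 neuroectoderm genes were higher and 5 lower. Epithelial genes were higher at 11 of 19 and lower at 0, led by the splicing regulator ESRP1 (3.38), CLDN6 (2.90) and CDH1 (2.44), E-cadherin. Fibroblast and stroma genes were lower at 6 of 8 and extracellular matrix genes at 8 of 19 with 1 higher, including smooth muscle transgelin TAGLN (-4.31), the collagen COL1A2 (-1.98) and SPARC (-1.21). DPEP3 was at 107 TPM and listed at 0 in WT dEC, and AURKC (4.37), SLC39A4 (4.07), the hormone STC1 (4.06), TEX41 (39.5 against 1.53 TPM), BST2 (3.85), the WNT receptor FZD5 (3.79) and, with strand open, SIX3-AS1 (4.39) were higher. NNAT, DUSP23 and the natriuretic peptide NPPB were listed at 0, and the nitric oxide synthase NOS2 (-4.62), ACTC1 (-4.61), GAMT (-4.53), WNT2B (-4.16) and ANXA1 (-4.12) were lower. Of 16 unfolded protein response genes 7 were lower and 0 higher, CHAC1 at -2.27. In all 839 genes were higher and 1660 lower of 12605 (66.4% lower), and the share lower was 44.1% after median-ratio rescaling and 54.4% without mitochondrially encoded and ribosomal protein genes, which moved the median of all genes by 0.23 and 0.16.

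In dME, 3AKO cells had lower p53 target transcripts and higher endothelial and amnion-associated ones than WT cells. The cyclin-dependent kinase inhibitor CDKN1A (chromosome 6, 36676460 to 36687339) was 0.717 TPM against 63.7 in WT dME (-5.24), and 14 of 27 p53 targets were lower and 1 higher, with GDF15 at -3.04, FDXR at -2.24 and TP53INP1 at 1.02. Amnion or trophoblast genes were higher at 7 of 13 and lower at 1, such as VTCN1 (2.72), GABRP (2.64) and TFAP2A (2.08), and endothelial genes were higher at 4 of 7 and lower at 1, with CDH5 at 2.97, PECAM1 at 2.33 and LMO2 at -1.87. Interferon response genes were higher at 5 of 12 and lower at 0, IFIT1 at 2.14 and BST2 at 1.98. HOXB1, at 26.9 TPM, was listed at 0 in WT dME, and the lymphatic matrix gene CCBE1 (4.78), the NODAL co-receptor CFC1 (4.52), MFAP4 (4.38), the limb and craniofacial mesenchyme factor PRRX1 (4.16), the endothelial PLVAP (3.89), LIX1 (3.79), NPY (3.70), CRH (3.59) and SLC16A9 (3.52) were higher. NNAT (-6.26), the muscle actins ACTA1 (-6.07), ACTG2 (-4.83) and ACTC1 (-4.47), HSPA2 (-4.52), SRPX2 (-4.36), the WNT inhibitor DKK1 (-4.32) and CLEC1B (-4.33) were lower, and DUSP23 was listed at 0. Mesenchymal genes were lower at 8 of 18 and higher at 1, VIM at -1.53 and ZEB1 at 1.54. In all 1765 genes were higher and 728 lower of 13074 (29.2% lower), but 57.8% were lower after median-ratio rescaling, which moved the median of all genes by -0.30.

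DKO dME cells also had higher PLVAP (4.84), CCBE1 (3.67) and MFAP4 (3.72) than WT dME, and the endothelial genes CDH5 (2.19) and ERG (1.95) were higher, 3 of 7 in that list, with 0 lower. DPEP3, at 26.2 TPM, was listed at 0 in WT dME, and the fatty acid binding protein FABP7 (4.38), LCN15 (4.08), HHIPL2 (3.84), AURKC (3.66), PRSS51 (3.63) and TEX41 (3.55) were higher. NNAT (-6.33), the corticotropin releasing hormone binding protein CRHBP (-6.16), NKAIN4 (-5.34), DUSP23 (-4.99), ACTA1 (-4.77), CYP26A1 (-4.66), which degrades retinoic acid, ACTG2 (-4.38), CXCL14 (-4.01) and the neuropeptide GAL (-3.99) were lower, and AGPAT2 was listed at 0 against 31.7 TPM. Of 27 p53 targets 6 were lower and 1 higher, CDKN1A at -1.43, and in the imprinted list 4 of 19 were higher and 3 lower, PHLDA2 at -2.70 and DLK1 at 1.34. In all 1095 genes were higher and 689 lower of 12564 (38.6% lower; 49.8% after median-ratio rescaling, which moved the median of all genes by -0.12).

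Differentiation of WT cells to dEC went with lower pluripotency genes and higher neural genes. By size, 14 of 18 pluripotency core genes were lower and 0 higher, with the NODAL co-receptor TDGF1 at -8.23, the noncoding ESRG at -6.44 and POU5F1, or OCT4, at -4.89, and 10 of 12 neuroectoderm genes were higher and 1 lower. The eye and forebrain factor PAX6 (chromosome 11, 31784779 to 31818062) was 80.8 against 0.242 TPM (6.05), and DLK1 (296 against 2.28 TPM), OTX1 (5.43), NOS2 (5.41), DKK1 (5.21), the crest factor PAX3 (5.20), ZBTB16 (4.82), MUSTN1 (4.54) and ZFHX4 (4.45) were higher, with WNT1 at 31.7 TPM against a listed 0. Epithelial genes were lower at 13 of 20 and NODAL and TGF-beta genes at 10 of 13 with 1 higher, among them NODAL (-5.85) and CER1 (-5.51); GAL (-6.14), NTS (-5.55) and MGC32805 (-7.03) were lower, LEFTY1 was listed at 0 in WT dEC, NANOGP8 (-5.83) cannot be separated from NANOG with certainty, and FOXD3-AS1 was listed at 0 in WT dEC. In all 1511 genes were higher and 1166 lower of 12634 (43.6% lower, but 58.3% after median-ratio rescaling, which moved the median of all genes by -0.17).

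In WT dME against WT ES, mesoderm, BMP and extracellular matrix genes were higher. HAND1 (chromosome 5, 154474972 to 154478264), a heart and extraembryonic mesoderm factor, was 1168 against 15.5 TPM (6.18), 16 of 17 mesoderm genes were higher and 0 lower, 14 of 15 BMP genes were higher and 0 lower, and all 7 HOX genes compared were higher, HOXB6 at 5.85. Extracellular matrix genes were higher at 19 of 25 and lower at 1, with the collagen COL3A1 at 7.20, LUM at 6.56 and FN1 at 4.50, and CRHBP (7.29), NNMT (7.25), DKK1 (6.46), HAPLN1 (6.41), TGM2 (6.34), RSPO2 (6.29) and C8orf4 (6.08) were higher as well. Of 18 pluripotency core genes 16 were lower and 0 higher, with ESRG at -7.02, PRDM14 at -5.72 and SOX2 at -4.45. The metallothioneins MT1G (-6.87) and MT1H (-5.93), ZSCAN10 (-6.65), CRABP1 (-6.34), LEFTY1 (-6.02), MGC32805 (-6.72) and ABHD12B (-5.40) were lower. In all 1702 genes were higher and 1296 lower of 12464 (43.2% lower). The share lower was 50.03% without mitochondrially encoded and ribosomal protein genes and 73.2% when log values were averaged over cells.

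Both knockout clones moved along these routes by size. In 3AKO dEC against 3AKO ES, 9 of 12 neuroectoderm genes were higher and 2 lower, 8 of 9 neural crest genes higher and 0 lower, and 14 of 20 epithelial genes lower, with PAX3 at 6.82, WNT1 at 6.63, MUSTN1 at 6.51, COL2A1 at 6.41 and TPBG at 5.60, and with TDGF1 at -7.73, MT1G at -6.95, CLDN7 at -6.61, EPCAM at 0.241 against 112 TPM and PMAIP1 at -6.35. In DKO dEC against DKO ES, 10 of 12 neuroectoderm genes were higher and 0 lower, 4 of 6 neural crest genes higher and 1 lower, and 3 of 20 epithelial genes lower; DLK1 (9.22), PAX6 (6.12), FEZF1 (5.18), DLX5 (4.88) and SIX3 (4.76) were higher, and MT1G and CST1 were listed at 0 against 237 and 922 TPM. In dME against ES, 17 of 17 mesoderm genes were higher in both clones, HAND1 being at 610 TPM in 3AKO dME and 793 in DKO dME. HAPLN1 (8.64), HAS2 (7.41), EPAS1 (7.11), H19 (7.03), RGS4 (6.89) and MEIS1 (6.85) were higher in 3AKO dME, and COL3A1 (7.56), ANXA1 (7.51), LUM (6.87), MYL4 (6.83) and PMP22 (6.24) in DKO dME. MT1G was lower in both, at -6.75 and -7.43, as was ESRG, at -5.06 and -6.97. Of the genes compared, 1879 were higher and 1001 lower in 3AKO dEC (median shift -0.11 after median-ratio rescaling), and 1113 and 1381 in DKO dEC. In 3AKO dME 2993 were higher and 937 lower (23.8% lower; 43.9% after median-ratio rescaling and 37.1% without mitochondrially encoded and ribosomal protein genes, which moved the median of all genes by -0.31 and -0.18). In DKO dME 2182 were higher and 1155 lower (34.6% lower; 46.7% without those genes, with shifts of -0.11 and -0.14).

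On day 2 of DNMT1 KO, 458 genes were higher and 349 lower than at day 0 of 12547, or 6.43%, against 3.21% between the WT ES replicates. The total of 807 fell to 451 among cells with 5000 or more genes and to 332 when log values were averaged over cells. The WT ES pair was not counted under these alternatives. The metallothioneins MT1G (-5.78), MT1E (-3.59), MT1H (-2.65) and MT1X (-1.93), which bind zinc, were lower, as were TXNIP (-2.86), ELL3 (-2.27), CLDN7 (-2.22), KDELR3 (-2.14), BNIP3 (-1.99) and PCSK5 (-1.95). The acetyl-CoA synthetase ACSS2 (2.26), FABP3 (2.93), LEFTY1 (2.73), IL21R (3.25), ZNF287 (2.49), INPP5J (2.38) and TMEM132A (2.17) were higher, and the pseudogene names SRP9P1 (19.6 TPM against a listed 0) and FABP5P7 (2.78) are uncertain. The unfolded protein response list had a median of 0.64, above all 10000 random lists, though 1 of 16 members passed 1 on the log2 scale. UHRF1, the partner of DNMT1 at replicating DNA, was 33.2 against 14.0 TPM (1.18).

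At day 8 germline and cancer-testis genes were higher than at day 0. MAGEA3 (chromosome X, 152698752 to 152702347) was 66.3 against 0.0192 TPM (6.05), with the close paralogue MAGEA6 at 5.37 sharing sequence with it, and 10 of 14 germline genes were higher and 0 lower, including RPL10L (5.05), MAEL (4.68), DAZL (4.31) and SYCP3 (3.62). In the cancer-testis list 4 of 5 were higher. VCX3A (5.75), GTSF1 (5.60), which acts in the piRNA pathway, and ERVH48-1 (5.89) were higher, and DSCR8 was at 47.7 TPM against a listed 0. Of 19 imprinted genes 11 were higher and 0 lower, with NNAT at 5.89, PLAGL1 at 4.95 and MEG3 at 3.76, and 21 of 42 histone genes were higher and 0 lower. NODAL and TGF-beta genes were higher at 8 of 13 and lower at 1, CER1 being at 148 TPM against a listed 0 and NODAL at 4.69, and mesenchymal genes were higher at 11 of 17. CST1 (7.10) was higher, NPPB, at 90.6 TPM, was listed at 0 on day 0, and SLC25A3P1 (7.27) has a pseudogene name. The tryptophan-degrading IDO1 (-4.18), EPS8L2 (-3.58), TSPO (-3.02), the lipase LPL (-2.72), CRYM (-2.68), TNNI3 (-2.65), BIK (-2.56), HAPLN3 (-2.51), SIGIRR (-2.45) and CHGA (-2.43) were lower. In all 1525 genes were higher and 918 lower of 13256 (37.6% lower). Cells at day 8 had a median of 7547 detected genes, against 11962 at day 0, and among cells matched on detected genes 52.1% of the differing genes were lower.

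**Figure D4:**
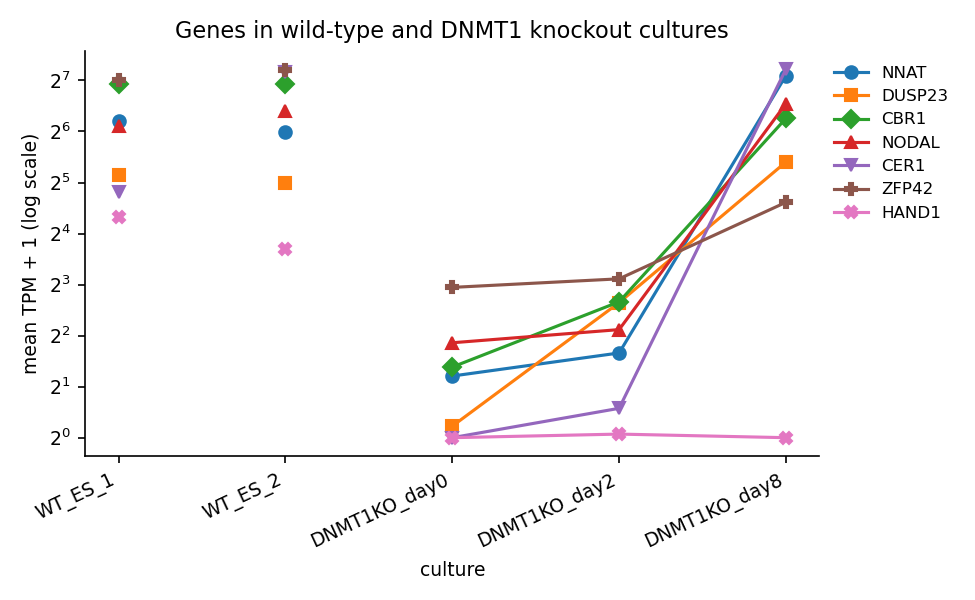
Mean TPM + 1 on a log axis (vertical) of NNAT, DUSP23, CBR1, NODAL, CER1, ZFP42 and HAND1 in the WT ES cultures and at DNMT1 KO days 0, 2 and 8 (horizontal), 1 line per gene. NNAT goes from 1.31 to 136 TPM and CBR1 from 1.61 to 75.5 between days 0 and 8, while HAND1 is listed at 0 at both.

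Shares of cells at 10 TPM or more for lineage markers follow, with exact Clopper-Pearson 95% intervals that cover counting error only. NANOG was at this level in 89.8% (81.5 to 95.2) and 84.4% (75.3 to 91.2) of cells in the WT ES cultures, 47.8% (37.3 to 58.5) in 3AKO ES and 86.7% (77.9 to 92.9) in DKO ES, whereas POU5F1 was at it in 97.8% or more of cells in each of these cultures. PAX6 was found in 44 of 83 (41.7 to 64.1%), 46.2% (35.6 to 56.9) and 65.9% (55.3 to 75.5) of WT, 3AKO and DKO dEC cells respectively, and LHX2 in 4.82% (1.33 to 11.9), 1.10% (0.0278 to 5.97) and 31.9% (22.5 to 42.5). HAND1 was found in 97.8%, 96.8% and 98.8% of WT, 3AKO and DKO dME cells, GATA4 in 46.2% (35.6 to 56.9), 17.0% (10.1 to 26.2) and 30.2% (20.8 to 41.1), and TFAP2A in 24.2%, 42.6% and 39.5%. Residual POU5F1 was at this level in 43.4% (32.5 to 54.7), 29.7% (20.5 to 40.2) and 57.1% (46.3 to 67.5) of WT, 3AKO and DKO dEC cells, and in 37.4% (27.4 to 48.1), 59.6% (49.0 to 69.6) and 48.8% (37.9 to 59.9) of the dME cells. SOX17 and FOXA2, markers of endoderm, were at this level in 7.45% of cells at most in any culture, and HAND1 in 0 of 92 3AKO ES cells, which allows up to 3.26%. The proliferation marker MKI67 ranged from 33.7% at DNMT1 KO day 0 to 63.7% in DKO dEC.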

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

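The tests of distance between cells, of the split in 3AKO ES, of the DNMT1 KO days and of DNMT1 KO day 0 against 1 WT ES culture at a time were chosen after the results were seen; those of a WT ES subset were chosen after the patterns were seen but before their own results, and the other tests of the 367 genes lower in both clones were written before. Several genes differed from WT in opposite directions at different stages of the same clone. The difference between stages was not tested for any of them, and in dEC and dME each value is a size without a test. In 3AKO cells BMPER, a secreted BMP regulator, was lower than WT in ES cells (-1.68), higher in dEC (3.61) and lower in dME (-1.30). The forebrain factor FEZF1 (2.89 in ES, -1.56 in dEC) and the chemokine CXCL5 (2.62 in ES, -2.69 in dEC) were higher in ES cells and lower in dEC. The hyaluronan synthase HAS2 (-4.68 in ES, 1.34 in dME), MFAP4 (-1.77 in ES, 4.38 in dME) and NPY (-1.96 in ES, 3.70 in dME) were lower in ES cells and higher in dME. In DKO cells CST1 was at 4.09 in ES and -1.31 in dME, CYP26A1 at 1.23 in ES and -4.66 in dME, and LCN15 at -1.64 in dEC and 4.08 in dME. Of the ES differences limma called those of FEZF1 (adjusted p = 0.0164), CXCL5 (0.0143) and HAS2 (0.0161) in 3AKO and CYP26A1 (0.0346) in DKO, and not those of BMPER (0.195), MFAP4 (0.0867) or CST1 (0.217); NPY was not among the genes tested. CST1 differed between the WT ES cultures, at 7.59 and 343 TPM. No group had 4 to 10 cultures, so single cultures far from their group could not be looked for.

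Cells lay farther apart than in WT in all 6 knockout cultures, by 0.108 in 3AKO ES, 0.128 in DKO ES, 0.0684 and 0.0715 in 3AKO and DKO dEC and 0.0892 and 0.0550 in dME, and these cultures had fewer detected genes per cell, which may raise the distance. DNMT1 KO day 0, with WT-like DNMT1 mRNA, also lay above WT ES, by 0.0434, and by 0.0465 (SE 0.0133) in matched cells. In 3AKO dME the excess stayed at 0.0809 (SE 0.0190) in cells matched with WT dME, 0.1045 (SE 0.0389) in cells matched over the 13 cultures and 0.0844 and 0.0939 in the bands of detected genes with 20 or more cells per culture, each above the SD of 0.0309 between the WT ES cultures, which argues against lower detection as the whole cause; the thinnest band, with 10 WT and 9 3AKO cells, gave 0.0176. In DKO dEC and DKO dME the lower matched excess was -0.00997 (SE 0.0394) and 0.0157 (SE 0.0228), and no matched value exceeded that SD (a DKO dME band with 16 cells gave 0.0321). Lower detection could account for these, but with SEs of this size a true excess is not ruled out. The SD of 0.0309 also came from unmatched cells. In 65 matched cells per culture the WT ES replicates differed by 0.0156, and the DKO dME values of 0.0157 and 0.0241 were no smaller than that difference. Against the mean of the WT cultures, the 2 ways of matching gave 0.0506 (SE 0.0203) and -0.0114 (SE 0.0352) in 3AKO ES and 0.0703 (SE 0.0148) and 0.0310 (SE 0.0510) in DKO ES, and 3AKO dEC gave 0.0198 and 0.0219 with 0.0319 in a band. In all 4 bands 3AKO ES and DKO ES lay above both WT ES cultures, by 0.0324 to 0.1045 and 0.0337 to 0.0850, but no band had 20 cells in every ES culture. Detection and a true spread cannot be told apart in these 3 cultures, because few cells match and not every value exceeded that SD by more than its SE. A mixture of cell states, the clone and the culture stay open for 3AKO dME, and no biological explanation was tested.

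The 367 genes lower in both 3AKO ES and DKO ES, NNAT, ZFP42 and DUSP23 among them, could reflect chance high values in the shared WT ES cultures, the composition of TPM, a differentiating subset in WT ES, or any long-separated line. Against the WT dEC and dME cultures their median was lower in all 4 comparisons, nearest to 0 at -0.41, below all random lists, which argues against the shared WT ES cultures as the whole cause, and after each cell was rescaled without ribosomal protein and mitochondrially encoded genes 85.3% of them (313) stayed lower in both, which argues against composition. Of the 367, 91.0% stayed lower in both without the 12 and 17 WT ES cells at 10 TPM or more of a lineage marker, which argues against those cells as the whole cause. Only 13.9% did without the 20% of WT ES cells highest in each gene, but this trim lowers the WT mean of every expressed gene and so cannot decide. A subset of WT ES cells without these markers stays open. In DNMT1 KO day 0, which had WT-like DNMT1 mRNA, 54.8% were also lower, against 11.7% of genes matched on expression. With genes chosen against 1 WT ES culture and measured against the other, it was 48.4% and 38.7%, against 12.9% and 9.61% of matched genes. A difference of any other line from WT ES and loss of DNMT3A therefore cannot be told apart. The excess of lower over higher genes in 3AKO ES depended on the scaling, at 49.3% lower without ribosomal protein and mitochondrially encoded genes, over genes passing the filter as deposited, against 65.0% before, but at 61.2% after median-ratio rescaling, so its cause stays open.

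Genes low at DNMT1 KO day 0 against WT ES were higher at day 8. Of 35 genes with 10 TPM or more in both WT ES cultures and a difference of -3 or below, 30 (85.7%) were higher by 1 or more at day 8, and 17 then lay less than 1 below WT ES, while others such as ZFP42 (23.4 against 128 and 147 TPM) stayed far below. At day 2 it was 25.7%, which argues against chance low values at day 0, and among other genes of the same day 0 level 8.17% were higher at day 8, which argues against a general gain of low genes. Without the 20% of WT ES cells highest in each gene 85.71% stayed lower by 1 or more at day 0. The genes were chosen at -3 and needed only -1 here, so a subset may carry part of the difference. For most of the set the values argue only against a subset of up to 20% of WT ES cells as its whole source. They do not do so for single genes such as HAND1. The genes include CER1, NODAL, LEFTY1 and LEFTY2 of the NODAL pathway, and with 1 culture per day a difference in signalling or culture condition stays open beside loss of DNMT1; methylation was not measured and no biological explanation was tested.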

How the results depend on the processing

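The matched cells of the compared cultures were an alternative chosen after seeing the data; the others were planned. No paired analysis was run: the labels pair no cultures, and a fit of genotype plus stage over the ES, dEC and dME cultures was not planned. Values follow the order 3AKO ES, DKO ES, DNMT1 KO day 0, 3AKO dEC, DKO dEC, 3AKO dME, DKO dME, then WT dEC, WT dME, 3AKO dEC, 3AKO dME, DKO dEC and DKO dME against ES cells of their genotype, then days 2 and 8. The cause of a change was not tested unless stated.

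A pseudocount of 5 TPM gave 725, 683, 1791, 902, 1200, 1224, 826, 1426, 1874, 1569, 2353, 1181, 2000, 321 and 1209 differing genes, because it shrinks low genes, and 50.8% lower in WT dEC against ES. A filter of 20 TPM, which tests fewer genes, gave 684, 590, 1414, 760, 899, 1054, 620, 1174, 1465, 1223, 1764, 895, 1497, 204 and 840, and 50.1% lower in WT dEC against ES. No filter gave, without DNMT1 KO day 0, whose count stayed within 1.5 times, 2696, 2659, 3686, 4587, 4308, 3492, 4163, 4579, 4868, 6326, 4455, 5444, 1850 and 4495, with 46.4% lower in DKO ES and 50.2% at day 2. Averaging log values over cells, which counts missed detection as lower expression, gave 2573 genes in 3AKO ES, 2742 in DKO ES and 332 at day 2. The share lower then grew to 91.3% in 3AKO ES, 91.0% in DKO ES, 86.3% in 3AKO dEC, 91.1% in DKO dEC and 87.2% in DKO dEC against ES. It turned to 56.2% in DNMT1 KO day 0, 73.6% in 3AKO dME, 74.3% in DKO dME, 84.4%, 73.2%, 77.6%, 58.4% and 52.0% in WT dEC, WT dME, 3AKO dEC, 3AKO dME and DKO dME against ES, 61.1% at day 2 and 94.2% at day 8.

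Without mitochondrially encoded and ribosomal protein genes the share lower was 43.5% in 3AKO ES, 37.1% in DKO ES, 40.0% in 3AKO dEC and 50.03% in WT dME against ES. The filter was applied after that rescaling, so the genes compared changed as well. Median-ratio rescaling gave 41.8% in 3AKO dEC, 44.1% in DKO dEC, 57.8% in 3AKO dME and 58.3% in WT dEC against ES. In DKO ES it was 49.6% among cells with 5000 or more genes, 47.1% without WT ES replicate 2 (58.8% without WT ES replicate 1) and 47.4% among matched cells. Matched cells gave 48.8% in 3AKO dEC, 47.1% in DKO dEC against ES and 52.1% at day 8, and cells with 5000 or more genes gave 451 differing genes at day 2.

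limma without the trend called 4 genes in 3AKO ES and 0 in DKO ES (3799 and 3698 at an unadjusted p under 0.05), and without the filter 0, 0 and 0 (6239, 6091 and 8930). Averaged logs gave 5704, 5886 and 7751 calls and median-ratio rescaling 2588 and 2371 in 3AKO ES and DKO ES. Calls with all cells, with all 13 cultures in the fit and with a pseudocount of 0.1 TPM stayed within 1.5 times the count given. Leaving out a WT ES culture left no residual degrees of freedom and so no test.

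Matched cells gave distance differences of 0.0506 in 3AKO ES, 0.0703 in DKO ES, 0.0198 in 3AKO dEC, -0.0046 in DKO dEC, 0.0157 in DKO dME, -0.0107 at day 2 and 0.0494 at day 8. Matching over the 13 cultures gave -0.0114 in 3AKO ES, 0.0310 in DKO ES, -0.0332 in DNMT1 KO day 0, 0.0219 in 3AKO dEC, -0.0100 in DKO dEC, 0.0241 in DKO dME, 0.0030 at day 2 and 0.0406 at day 8. Counting genes at 5 TPM changed the difference in detected genes to -824 in 3AKO ES, -1542 in DKO dEC, -98 at day 2 and -2092 at day 8, and counting any TPM above 0 to -1891.8, -673.8, -1272 and -5084.5 in 3AKO ES, DNMT1 KO day 0, day 2 and day 8. At a threshold of 2, 40, 103 and 57 genes were lower in both clones in ES, dEC and dME, and 17, 35 and 67 higher. Of 300 values of named genes, none changed direction under the alternatives run on them, while 263 moved in size with averaged logs and 61 with median-ratio rescaling, 226 with a pseudocount of 0.1 TPM and 71 with cells of 5000 or more genes. These genes were named for the largest differences, so a change of direction was unlikely from the start. Those named against WT ES lay outside both cultures, so leaving out 1 of them could not reverse a direction. Of the shares of cells with each of 14 markers in the 13 cultures, 62 moved when counted at 1 TPM and 103 at 50 TPM. Both list medians printed kept their side under the alternatives run.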

Other observations

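The genes below were chosen after their values were seen, and no test was run for this section. Some genes were higher in DKO than in WT cells at every stage. DPEP3, a testis dipeptidase, was at 96.2, 107 and 26.2 TPM in DKO ES, dEC and dME cells, and at 3.66 TPM or less in every WT and 3AKO culture. AURKC, a kinase of meiosis, was at 40.4, 33.8 and 23.6 TPM in the DKO cultures and at 10.7 or less in the WT and 3AKO cultures. The zinc importer SLC39A4 was at 70.8, 55.6 and 82.1 TPM in DKO cells, against 19.1, 11.4 and 29.2 in 3AKO cells and 2.37 to 11.7 in WT cells. In the DNMT1 KO series DPEP3 went from 1.15 TPM at day 0 to 20.6 at day 8, AURKC from 3.39 to 15.1 and SLC39A4 from 7.35 to 53.2. BST2, an interferon-induced antiviral protein, was higher in both clones, at 206, 133 and 131 TPM in 3AKO cells and 196, 248 and 81.7 in DKO cells, against 16.3 to 32.4 in WT cells.

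Of the 35 genes low at DNMT1 KO day 0, 19 were also lower by 3 or more in 3AKO ES, 6 in DKO ES and 5 in both. The genes that were not higher by 1 or more at day 8 were BNIP3P17, listed at 0 at day 0 and at 0.52 TPM at day 8, ZNF826P (-0.01), ZNF680 (-0.23), FAM71F1 (-0.26) and HAND1, which was listed at 0 at both days. The WT ES level of HAND1 rests on few cells, with 4 of 88 and 2 of 90 at 10 TPM or more. CBR1 was at 120 and 121 TPM in the WT ES cultures, 1.61 at day 0, 5.33 at day 2 and 75.5 at day 8. DNMT3L was at 7.39 TPM in DKO dME and at 0.73 or less in the other cultures, but it was detected at 1 TPM in only 6 of 86 DKO dME cells, so a few cells carry that mean.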
